A study of Mus musculus with 13 samples.

How the data were processed

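RNA of total liver from female C57BL/6 mice was measured on 13 single-colour Illumina MouseRef-8 BeadArrays. The labels name 3 naive samples and samples taken after 1 week (3), 4 weeks (4) and 6 weeks (3) of TAA, which in liver-injury work is the usual short form of the hepatotoxin thioacetamide. The labels give no dose, route or dosing scheme, and they do not say whether the samples of a group are separate animals. The p-values therefore measure only the spread between these samples.

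The raw table deposited for the series holds, per the file headers, the mean bead intensity of each probe on each array, neither normalized nor background-subtracted. Beside each intensity it holds, per the file headers, a detection p-value, which ranks the probe's signal among the negative control beads of that array. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. The value table deposited by the authors holds log2 values that are centred on each probe near 0. Its normalization and its centring are not stated. Differences of its group means from naive followed those of quantile-normalized log2 intensities computed from the raw table, with r = 0.998 and a slope of 0.905 across probes. Its scale was therefore read as log2 and its direction as higher for brighter. Single arrays were not matched between the tables. The mean over all its values was 0.00751. The column medians were -8.67e-04, -6.07e-04 and -9.75e-04 for the naive samples and -0.00176, -0.00116 and -4.85e-04 at 1 week. They were -7.00e-04, 2.87e-04, 1.98e-04 and -1.98e-04 at 4 weeks, and 0.00115, 0.00134 and 3.67e-05 at 6 weeks. The raw table was analysed, and the value table served as an alternative.

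Columns of the raw table carry a group and a letter, and each was given its group from its own heading. Replicate numbers stand only in the labels of the value table, so the letters below are those of the raw table. Of the 25697 probes, 23978 had a gene symbol in the annotation supplied and 1719 had none. No probe had several symbols. The probes carried 16590 symbols. Gene identifiers matched 23962 of the named probes to a current symbol, accessions matched 9 more, and 7 kept the symbol they had. The match updated 8 symbols. The annotation supplied gives no genome build or coordinates, so genes are named by symbol only.

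Intensities were background-corrected and normalized with neqc in limma 3.58.1 under R 4.3.3, with an offset of 16 and quantile normalization, the mean and spread of the negative controls being inferred from the detection p-values. Probes with a detection p-value under 0.01 on at least 3 arrays were kept. This left 11212 probes, 653 of them without a symbol. One probe per gene was tested, the one with the highest mean over all arrays, which gave 8027 genes, and 1935 of these had further probes past the filter. One limma model (lmFit and eBayes) was fitted to the 13 arrays with a mean per group, and 6 comparisons were drawn from it, each with a two-sided moderated test. A gene was called when its p-value, adjusted by Benjamini and Hochberg over the genes of the comparison, was under 0.05. Log2 changes are given with their standard error (SE). For arrays, depth is the brightness over background, and the number of arrays limits the precision.

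A gene detected on no array of the dimmer group was given a lower bound of its fold. The bound sets the brighter group's mean of normalized log2 values against the dimmer group's mean of, per array, the higher of the lowest detected signal and the probe's own signal. Medians of lists were also computed with such genes at their bound. For named genes detected on only some arrays of the dimmer group, the change was also computed with its undetected arrays at their lowest detected signal (floored), and printed where it was smaller by 0.2 or more, a choice made after the values had been seen.

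Before the data were examined, 34 lists of liver genes were written from general knowledge, covering cell types, liver zones, metabolism, injury and stress responses, sex-biased genes and tissues that might be carried over. Of these, 28 had at least 5 tested members and were tested with camera in limma at a preset correlation of 0.01, adjusted over all lists and comparisons together. The correlation estimated per list and the rotation test fry served as alternatives. The erythroid list reached 5 because Hbb-bt, entered as another symbol of Hbb-b2, passed the detection filter where Hbb-b2 did not. The remaining 6 lists had fewer than 5 tested members and were only described. In 10 of the 168 list tests the median, the mean and the test differed in sign, and 0 of those were called. Members were counted as called both over all genes and adjusted over the list alone.

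The genes named were fixed by a rule written before the data were examined. For each comparison with naive it takes the 10 called genes with the largest rise and the 10 with the largest fall whose arrays do not overlap and which were detected in both groups, and for each comparison between TAA times the 5 and 5. It adds up to 5 genes per direction detected on every array of one group and no array of the other, the 3 called members with the largest change in each direction of each list, and a fixed set of key genes. Among the key genes, Epcam, Spp1, Cd68 and Mki67 had no named probe, and Cd24a, Prom1, Ccl2, Ccr2, Tnf and Tnfsf12 did not pass the detection filter. Genes named outside the rule are marked as chosen after their values were seen.

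The files name no BeadChip or hybridization day. The arrays were therefore searched for a division that did not follow the groups, and 2 sets were read from the values. The first holds the naive arrays, 1-week array A and the 4-week arrays. The second holds 1-week arrays B and C and the 6-week arrays. Each comparison was refitted with the set as a fixed term, and where both groups had arrays in a set, within that set. With the fixed term, the difference between the sets is estimated from the 1-week arrays alone, as B and C against A. Changes of 1-week from naive arrays and of 4-week from 1-week arrays then use 1-week array A alone for the 1-week group. Changes of 6-week from 1-week arrays use 1-week arrays B and C alone. Since 1-week array A alone links the sets, a comparison of 6-week with naive or 4-week arrays rests on that link. These refits, a random term for the set and brightness as a covariate were chosen after the data had been seen. A replicate term was planned, and was run on the value table because only its labels carry replicate numbers.

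The 3 comparisons with naive share the naive arrays, which makes their changes correlate without any effect of TAA. The correlation of their changes was set against 20 simulations of 13 arrays without effects, and the overlap of their calls against the overlap that independent lists of the same sizes would give.

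The procedure was tested on simulated data with 200 changed genes of 8027. It recovered 2.99% to 19.4% of 1.5-fold changes, 59.7% to 74.6% of 2-fold changes and 97.0% to 100% of 4-fold changes, with 2 to 14 false calls and 0 calls of the wrong sign per comparison. A list planted in 3 comparisons was called in 3 of 3, and 0 of 156 other list tests were called. The simulated genes varied independently, so this does not show how often lists of correlated genes are called falsely. The alternatives tried were the source of the values, the background correction, the normalization between arrays, the detection filter, the probes per gene, the variance model, array weights, the arrays in the fit, the thresholds, the test for lists and leaving out each array. Left out of the comparisons were the probes without a symbol, which were tested apart, and probes below the detection filter.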

Results

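Gene expression was measured in 13 samples of total mouse liver, 3 naive and 3, 4 and 3 taken after 1, 4 and 6 weeks of TAA. The series title places the samples in a study of liver fibrosis after toxic injury. Mean intensity per array ran from 472 to 587 in naive samples, from 177 to 479 at 1 week, from 456 to 611 at 4 weeks and from 195 to 273 at 6 weeks. Between 9382 and 9624 probes were detected per naive array, between 8344 and 10358 at 1 week, between 10259 and 10980 at 4 weeks and between 9675 and 10269 at 6 weeks. The dimmest array, 1-week array C, had a signal at the upper decile of 2.13 times its background, against 8.42 times on 4-week array C. Across genes, which are not independent replicates, log2 intensities of arrays correlated with r from 0.953 to 0.99 within groups and from 0.904 to 0.98 between groups.

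The intensities of 7 genes divided the arrays in a way the groups do not. Erich5, Zxda, Ifngr2, Prf1, Pisd-ps2, Rhbdl2 and Gm7609 were each at least 1 log2 unit higher on every 6-week array and on 1-week arrays B and C than on every other array, with gaps from 1.12 for Gm7609 to 2.78 for Erich5. Another probe of Ifngr2 did not follow this division, with changes from naive of -0.20, 0.43 and -0.04 at 1, 4 and 6 weeks against 1.53, -0.56 and 2.21. These 2 array sets cross the 1-week group only. Values with the set as a term in the model, called set-adjusted here, are printed beside the others. For 1 week against naive and 4 weeks against 1 week, set-adjusted changes set 1-week array A alone against the other group. For 6 weeks against 1 week they use 1-week arrays B and C alone. Changes within a set repeat these set-adjusted changes and do not check them. Changes are log2 ratios of quantile-normalized intensities, so each is relative to the other genes of the array. A floored change is one with the undetected arrays of a partly detected group at their lowest detected signal.

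The comparison of 1 week of TAA with naive liver asked what the early response was. Gsta1, a glutathione transferase that detoxifies electrophiles, rose by 8.03 ± 0.48 (SE, n = 3 and 3, adjusted p = 4.24e-07; set-adjusted 7.81). It was detected on 1 of the 3 naive arrays, and its floored change was 7.36, so the size of the rise is uncertain. Gsta2 of the same family rose by 5.32 ± 0.47 and the carbonyl reductase Cbr3 by 4.08 ± 0.50 (set-adjusted 5.17 and 3.6). The glutamate transporter Slc1a2, which marks hepatocytes around the central vein, fell by 4.33 ± 0.31 (adjusted p = 1.61e-06; set-adjusted -5.16). Its other probes changed by -2.55 and -4.12. Serpina12 fell by 4.39 ± 0.50 (floored -4.16) and ornithine aminotransferase, Oat, by 3.03 ± 0.37.

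At 1 week 2051 of 8027 genes were called, 1067 higher and 984 lower, and 3028 had an unadjusted p under 0.05. The arrays of 1927 of the called genes did not overlap between the groups, as for 36.3% of all genes, where chance gives 10%. A fit of the 1-week and naive arrays alone, in which only the variance differs, called 1099. With the set in the model 1148 genes were called, 931 of them among the 2051. Within the first set, 1-week array A against the 3 naive arrays, 2050 of the 2051 genes kept their sign. This was nearly fixed in advance, since array A helped to give the calls and the arrays of 1927 genes did not overlap.

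Spink1, Gpnmb, Akr1c18 and Mmp12 were detected on every 1-week array and no naive array. Spink1, a trypsin inhibitor, was at least 14.3-fold higher (adjusted p = 1.74e-04), and the macrophage glycoprotein gene Gpnmb at least 11.7-fold higher (adjusted p = 7.26e-05). Akr1c18 was at least 11.7-fold and the macrophage elastase Mmp12 at least 6.18-fold higher (adjusted p = 5.29e-05 and 1.79e-05). In the other direction Cpsf4l was at least 6.46-fold and the steroid dehydrogenase Hsd3b5 at least 3.58-fold lower (adjusted p = 9.39e-05 and 3.70e-04).

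Proliferation genes rose together at 1 week. Of 23 cell cycle genes 16 rose, 19 adjusted over the list alone, with a median of 1.59 (set-adjusted 1.17; adjusted p = 1.01e-08, and 0.315 with an estimated correlation). Cdc20, which releases cells from metaphase, changed by 2.90 ± 0.60 (floored 2.55; set-adjusted 2.18, adjusted p = 0.101) and the replication helicase Mcm6 by 2.74 ± 0.36 (set-adjusted 2.16). Among 14 p53 targets 8 rose, 9 adjusted over the list alone, with a median of 1.03 (set-adjusted 0.88; adjusted p = 0.0101, and 0.20 with an estimated correlation). Phlda3 was at least 4.62-fold higher (adjusted p = 7.55e-06), and Cdkn1a, which arrests the cycle, rose by 2.34 ± 0.63 (set-adjusted 2.34, adjusted p = 0.113). Of 25 glutathione and NRF2 genes 12 rose and 2 fell, 15 and 2 adjusted over the list alone, with a median of 1.02 (set-adjusted 0.66; adjusted p = 6.30e-05, and 0.358 with an estimated correlation). Nqo1, another NRF2 target, rose by 1.04 ± 0.20 (set-adjusted 1.17). The integrated stress genes Asns and Atf3 were at least 4.79-fold and 2.23-fold higher (adjusted p = 4.43e-05 and 1.31e-04), while Chac1 fell by 2.40 ± 0.20 (floored -1.76). Their list, endoplasmic reticulum and integrated stress response, was not called at 1 week and had a set-adjusted median of -0.53.

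Macrophage genes rose as well, 7 of 21 up and 1 down, 10 and 1 adjusted over the list alone (median 0.61, set-adjusted 1.01; adjusted p = 8.99e-04, and 0.481 with an estimated correlation). Trem2, a lipid receptor of scar-associated macrophages, was at least 3.05-fold higher (adjusted p = 9.71e-04) and Lgals3 rose by 2.30 ± 0.30, while the scavenger receptor Cd163 fell by 1.38 ± 0.21. All 7 MHC class II genes had positive changes, and 4 of them rose, 7 adjusted over the list alone (median 1.01, set-adjusted 1.71; adjusted p = 0.00439, and 0.481 with an estimated correlation). H2-Aa rose by 1.46 ± 0.28. The matrix genes were not called as a list (adjusted p = 0.518), with 2 of 22 up and 1 down. Col3a1 rose by 1.51 ± 0.36 (floored 0.98; detected on 3 of 3 and 1 of 3 arrays). Col1a1 was detected on no array of either group, and Acta2, the smooth muscle actin of myofibroblasts, changed by -0.34 ± 0.51 (adjusted p = 0.671). Timp1, an inhibitor of matrix proteases, was at least 1.53-fold higher (adjusted p = 0.00366; set-adjusted 1.38, adjusted p = 0.0559). Tnfrsf12a, the receptor of the progenitor mitogen TWEAK, rose by 2.30 ± 0.33 (set-adjusted 2.09), and Afp was at least 2.29-fold higher (adjusted p = 0.00350; detected on 2 of 3 arrays).

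Several lists of hepatocyte genes were lower at 1 week, but the list of secreted protein and identity genes was not called (median -0.20, adjusted p = 0.172, and 0.0375 with the array set). Of 18 pericentral hepatocyte genes 14 fell and 1 rose, 15 and 1 adjusted over the list alone (median -1.23, set-adjusted -1.51; adjusted p = 5.74e-08, and 0.0737 with an estimated correlation). Glul, glutamine synthetase of the last hepatocytes before the vein, was at least 1.93-fold lower (adjusted p = 9.13e-04). Cyp2e1, which activates TAA, fell by 1.27 ± 0.20 and Cyp1a2 by 1.55 ± 0.30 (set-adjusted -1.34 and -1.52). The 15 periportal genes were not called as a list (median -0.07, adjusted p = 0.880).

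Among cholesterol synthesis genes 12 of 17 fell, also adjusted over the list alone (median -0.75, set-adjusted -0.81; adjusted p = 2.95e-05, and 0.335 with an estimated correlation), among them Tm7sf2 by 1.39 ± 0.26. Of 17 bile acid genes 10 fell and 2 rose, 10 and 3 adjusted over the list alone (median -1.06, set-adjusted -1.32; adjusted p = 0.00439, and 0.335 with an estimated correlation), with Cyp7b1 down by 1.77 ± 0.20. Female-biased genes fell in 5 of 7 cases, also adjusted over the list alone (median -1.82, set-adjusted -2.11; adjusted p = 0.00243, and 0.20 with an estimated correlation), and Cyp2b13 fell by 2.96 ± 0.64. The other lists called lower were cytochrome P450 (median -0.33, 11 of 28 down and 4 up; adjusted p = 0.0343), fatty acid oxidation (-0.32, 5 of 21; 0.0198), urea cycle and amino acid catabolism (-0.29, 4 of 21 and 1 up; 0.0212) and acute phase (-0.55, 5 of 18; 0.00545). With an estimated correlation these 4 had adjusted p = 0.481, 0.486, 0.486 and 0.481, and set-adjusted medians of -0.38, -0.43, -0.30 and -0.71. In all, camera called 13 of 28 lists with its preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05, and fry called 14.

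**Figure D1:**
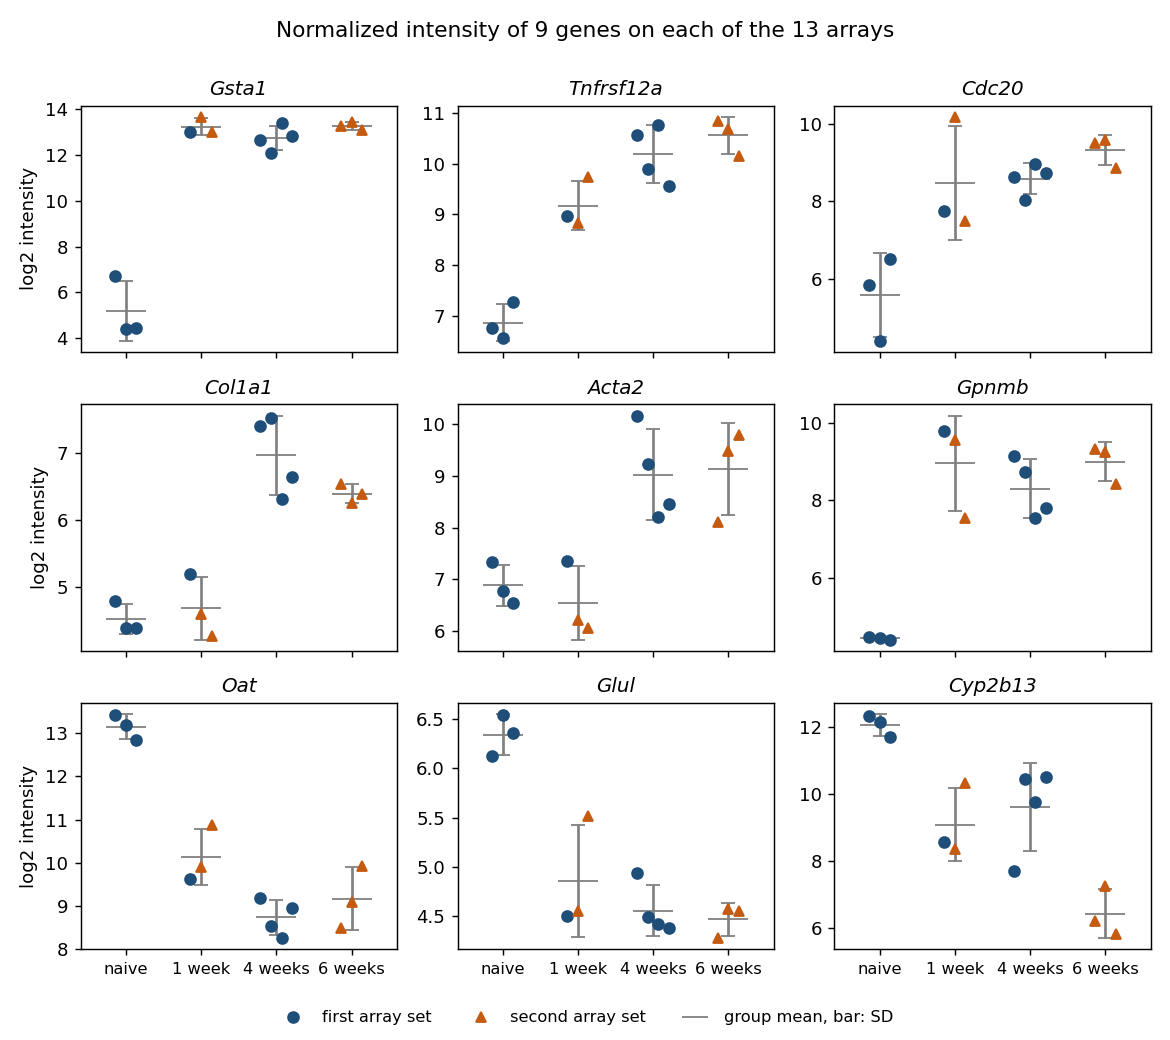
Log2 intensity of 9 genes on each of the 13 arrays by group, with the group mean and SD; circles mark the first array set and triangles the second. Gsta1, detected on 1 of 3 naive arrays, was higher at all 3 times, while Col1a1 and Acta2 were called higher at 4 and 6 weeks only.

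The comparison of 4 weeks of TAA with naive liver asked what was changed once injury had lasted. Both groups lie in the first array set, so set-adjusted changes equal the others. Gsta1 rose by 7.54 ± 0.45 (n = 4 and 3, adjusted p = 8.09e-08) (floored 6.87), the tetraspanin Cd63 by 4.91 ± 0.28 and Cbr3 by 4.87 ± 0.47. Tnfrsf12a rose by 3.32 ± 0.31 (adjusted p = 6.52e-06). Col1a1, a chain of the main scar collagen, was at least 2.95-fold higher (adjusted p = 3.94e-05), and Acta2 rose by 2.14 ± 0.47 (adjusted p = 0.00397). The other 3 probes of Acta2 changed by 0.39, 1.32 and 0.52. Oat fell by 4.43 ± 0.34, and Slc1a2 was at least 34.6-fold lower on the probe tested (adjusted p = 4.24e-08). The other probes of Slc1a2 changed by -2.88 and -5.11, so the size of its fall is uncertain.

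At 4 weeks 2260 genes were called, 1222 higher and 1038 lower, and 3190 had an unadjusted p under 0.05. The arrays of 2201 did not overlap, as for 45.4% of all genes, where chance gives 5.71%. The fit with the set in the model called 2420 genes, 2235 of them among the 2260. A fit of these 7 arrays alone, whose changes are the same by construction and only the variance differs, called 3145.

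Ly6d, a surface protein of epithelial cells, was at least 25.5-fold higher than in naive liver (adjusted p = 8.95e-06). Phlda3 was at least 10.1-fold, Tinag at least 10-fold and Spink1 at least 9.95-fold higher (adjusted p = 8.09e-08, 2.70e-07 and 1.13e-04). Detected on no 4-week array, Nxpe2 was at least 7.56-fold and Lrtm1 at least 5.74-fold lower (adjusted p = 7.56e-06 and 2.63e-04).

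Matrix genes rose at 4 weeks, 14 of 22 with 0 down and 17 adjusted over the list alone (median 0.91, or 0.87 with undetected genes at their bound; adjusted p = 7.12e-06, and 0.430 with an estimated correlation). Elastin, Eln, rose by 2.05 ± 0.43, Sparc by 1.78 ± 0.36 and Col3a1 by 1.69 ± 0.33, and the floored changes of Eln and Col3a1, each detected on 1 of 3 naive arrays, were 1.55 and 1.16. Col1a2, also detected on 1 of 3, changed by 0.61 ± 0.28 (adjusted p = 0.120). Of 18 matrix turnover genes 8 rose, 10 adjusted over the list alone (median 0.67, or 0.59 at the bounds; adjusted p = 0.00263, and 0.480 with an estimated correlation). Mmp2, the gelatinase of stellate cells, rose by 2.36 ± 0.49, and the crosslinking enzyme Lox was at least 1.5-fold higher (adjusted p = 4.78e-04). Stellate cell genes rose in 5 of 17 cases, also adjusted over the list alone (median 0.48, or 0.40 at the bounds; adjusted p = 0.00696, and 0.481 with an estimated correlation). Desmin, Des, and Pdgfrb, both markers of stellate cells, changed by 0.18 ± 0.30 and 0.48 ± 0.25 (adjusted p = 0.692 and 0.173).

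Cholangiocyte and progenitor genes rose, 8 of 14 by both counts, that is also adjusted over the list alone (median 0.93, or 0.80 at the bounds; adjusted p = 6.34e-05, and 0.255 with an estimated correlation). Cldn4, a tight junction gene of bile ducts, was at least 4.07-fold higher (adjusted p = 3.38e-04) and the keratin Krt23 rose by 2.33 ± 0.32. Krt19, detected on no naive array and 2 of 4 arrays at 4 weeks, was not called (adjusted p = 0.119). Krt7 and Sox9, detected on 2 and 1 of 3 naive arrays, changed by 0.46 ± 0.25 and 0.75 ± 0.32 (adjusted p = 0.193 and 0.0965). Macrophage genes rose in 8 of 21 cases and fell in 1, 8 and 2 adjusted over the list alone (median 0.41; adjusted p = 0.0275, and 0.639 with an estimated correlation). Gpnmb was at least 7.46-fold and the fractalkine receptor Cx3cr1 at least 1.57-fold higher (adjusted p = 5.83e-05 and 0.00749). Adgre1, Clec4f, Timd4 and Marco, which mark resident macrophages, were not called (adjusted p = 0.495, 0.852, 0.204 and 0.824). The interferon-induced chemokine Cxcl10 rose by 2.46 ± 0.40 while Cxcl9 fell by 2.03 ± 0.44. Lymphotoxin beta, Ltb, was at least 1.09-fold higher (adjusted p = 0.00661).

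Cell cycle genes stayed high at 4 weeks, 17 of 23 up and 1 down, 18 and 1 adjusted over the list alone (median 1.71, or 1.35 at the bounds; adjusted p = 1.72e-07, and 0.358 with an estimated correlation). The mitotic kinase Cdk1 was at least 4.22-fold higher (adjusted p = 9.67e-04), and Tk1, which salvages thymidine, fell by 1.05 ± 0.21. Of the p53 targets 8 of 14 rose by both counts, also adjusted over the list alone (median 0.86; adjusted p = 4.95e-04, and 0.117 with an estimated correlation), with Cdkn1a up by 3.55 ± 0.59. Of the glutathione and NRF2 genes 14 of 25 rose and 1 fell, 16 and 2 adjusted over the list alone (median 0.93, or 0.82 at the bounds; adjusted p = 1.23e-06, and 0.293 with an estimated correlation), and Nqo1 rose by 1.68 ± 0.19.

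Pericentral genes were lower in 13 of 18 cases, 13 down and 1 up adjusted over the list alone (median -1.11; adjusted p = 4.32e-08, and 0.0737 with an estimated correlation). Glul was at least 2.43-fold lower (adjusted p = 9.64e-05) and Cyp2c50 fell by 2.32 ± 0.32. Of 21 urea cycle and amino acid genes 12 fell, 14 adjusted over the list alone (median -0.81; adjusted p = 4.32e-08, and 0.191 with an estimated correlation), among them the proline oxidase Prodh by 2.57 ± 0.24 and Agxt by 2.0 ± 0.19. Acute phase genes fell in 13 of 18 cases, 15 adjusted over the list alone (median -1.39; adjusted p = 1.76e-06, and 0.277 with an estimated correlation), with the endotoxin-binding protein gene Lbp down by 2.05 ± 0.28. Bile acid genes fell in 11 of 17 cases and rose in 1, also adjusted over the list alone (median -1.31, or -1.15 at the bounds; adjusted p = 5.17e-05, and 0.20 with an estimated correlation). Female-biased genes fell in 5 of 7 cases, 6 adjusted over the list alone (median -1.47; adjusted p = 8.29e-04, and 0.163 with an estimated correlation), and Cux2, a female-specific liver factor, fell by 2.38 ± 0.31. Cyp2e1 fell by 0.83 ± 0.18, whereas Cyp1a2, Alb and Hnf4a were not called (adjusted p = 0.132, 0.146 and 0.752). The lists of cytochrome P450, secreted protein, interferon and male-biased genes were lower with medians of -0.35, -0.40, -0.56 and -0.40 (adjusted p = 0.0269, 0.00677, 0.0178 and 0.0379). With an estimated correlation these 4 had adjusted p = 0.481, 0.489, 0.489 and 0.430. In all, camera called 17 of 28 lists, and 0 with an estimated correlation, where 8 had an unadjusted p under 0.05, and fry called 16. With the first set alone 16 lists were called, each among the 17.

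**Figure D2:**
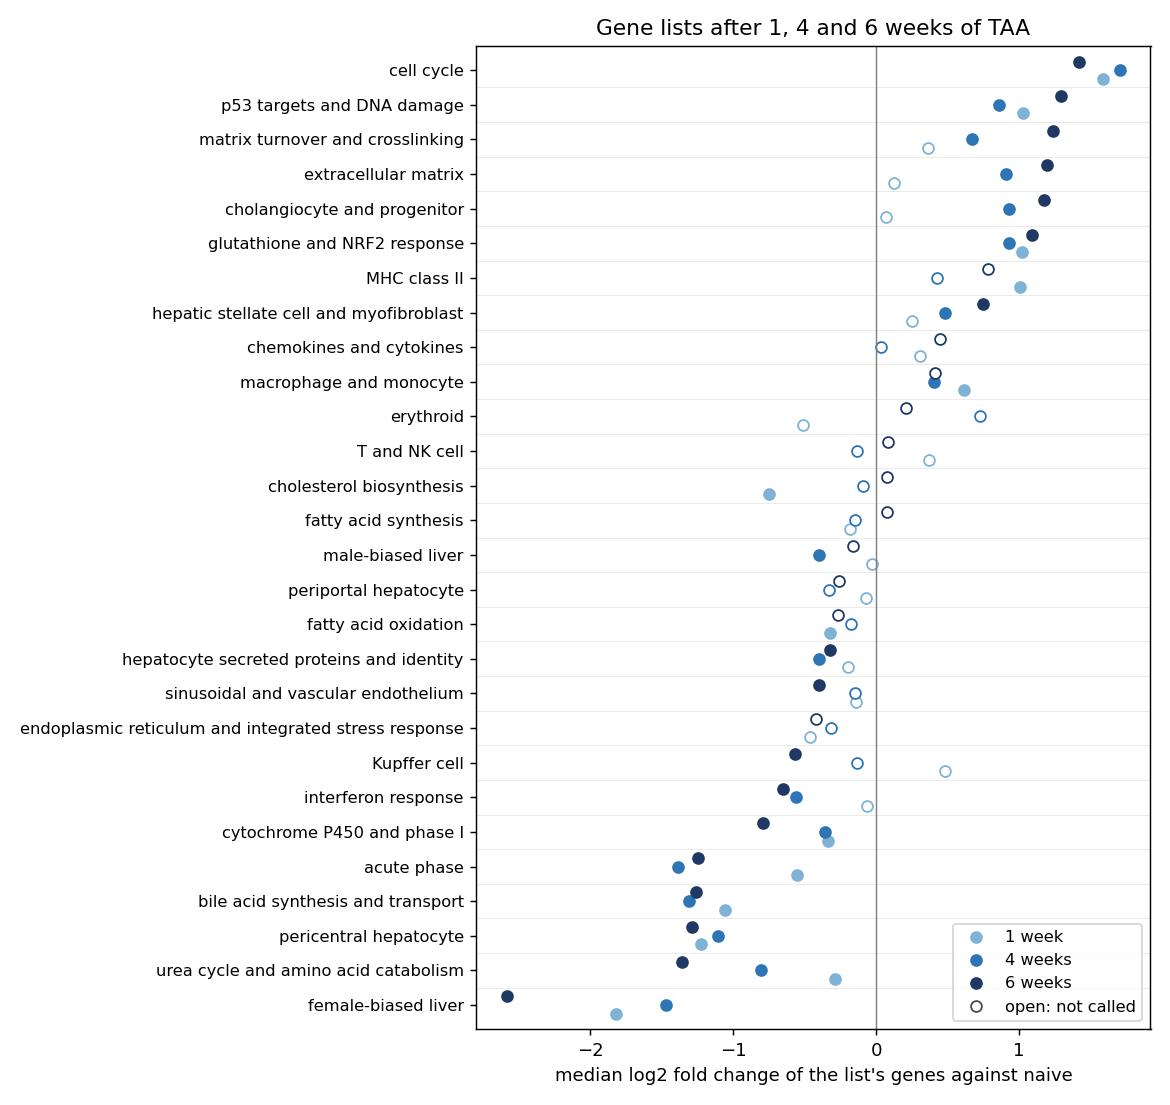
Median log2 change of the 28 tested gene lists against naive liver at 1, 4 and 6 weeks of TAA; filled points were called with the preset correlation of 0.01, open points were not, and 0 lists were called with an estimated correlation. The matrix list moved from 0.13 at 1 week to 0.91 at 4 weeks and 1.19 at 6 weeks.

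The comparison of 6 weeks of TAA with naive liver covered the longest exposure, and no array set holds arrays of both groups. Gsta1 rose by 8.07 ± 0.48 (n = 3 and 3, adjusted p = 1.33e-07; set-adjusted 7.73, floored 7.4), Cd63 by 4.78 ± 0.30 and Tnfrsf12a by 3.68 ± 0.33 (set-adjusted 5.10 and 3.37). Mmp2 rose by 3.34 ± 0.53 (adjusted p = 2.50e-04; set-adjusted 4.18) and Emp1, an epithelial membrane protein gene, by 3.62 ± 0.51 (set-adjusted 4.91). Cyp2b13 fell by 5.61 ± 0.64 (adjusted p = 2.68e-05; set-adjusted -6.37) and Oat by 3.99 ± 0.37 (set-adjusted -4.74).

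At 6 weeks 3118 genes were called, 1800 higher and 1318 lower, and 3845 had an unadjusted p under 0.05. The arrays of 3033 did not overlap, as for 52.7% of all genes, where chance gives 10%. With the set in the model 934 genes were called, 818 of them among the 3118, and 97.4% of the 3118 kept their sign.

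Ly6d was at least 44.1-fold and Gpnmb at least 12-fold higher (adjusted p = 3.96e-06 and 2.08e-05; set-adjusted adjusted p = 0.00431 and 0.00282). Slc1a2 was at least 30.8-fold and the transporter Slc22a26 at least 16.7-fold lower on the probes tested (adjusted p = 9.15e-08 and 8.31e-06; set-adjusted 2.00e-06 and 0.00332). The other probes of Slc1a2 changed by -3.00 and -4.93.

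Of the 22 matrix genes 15 rose and 1 fell, also adjusted over the list alone (median 1.19, set-adjusted 1.51, or 1.08 at the bounds; adjusted p = 2.83e-04, and 0.481 with an estimated correlation). Col3a1 rose by 2.57 ± 0.36 (floored 2.04) and Lum by 2.01 ± 0.49 (set-adjusted 3.09 and 3.45). Col1a2, detected on 1 of 3 naive arrays, rose by 1.20 ± 0.30 (floored 0.76; set-adjusted 1.00, adjusted p = 0.260), and Col1a1 was at least 1.98-fold higher (adjusted p = 3.0e-04; set-adjusted 0.00845). Matrix turnover genes rose in 11 of 18 cases, 13 adjusted over the list alone (median 1.24, set-adjusted 1.72, or 0.88 at the bounds; adjusted p = 2.72e-04, and 0.392 with an estimated correlation), with Loxl1 up by 2.44 ± 0.49. Stellate cell genes rose in 9 of 17 cases, also adjusted over the list alone (median 0.75, set-adjusted 1.47, or 0.50 at the bounds; adjusted p = 0.00590, and 0.481 with an estimated correlation). Ccn2, a growth factor target of TGF-beta, rose by 2.36 ± 0.44 and Acta2 by 2.25 ± 0.51 (set-adjusted 3.35 and 3.48). The other 3 probes of Acta2 changed by -0.01, 1.59 and -0.25. Tgfb1 itself changed by -0.06 ± 0.26 (adjusted p = 0.888).

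Cholangiocyte and progenitor genes rose in 11 of 14 cases, 12 adjusted over the list alone (median 1.17, set-adjusted 1.00, or 0.96 at the bounds; adjusted p = 1.40e-04, and 0.277 with an estimated correlation). Cldn4 was at least 8.37-fold higher (adjusted p = 4.47e-05; set-adjusted 0.0263). Sox9 and Krt7 rose by 1.16 ± 0.34 and 0.79 ± 0.27 (floored 0.94 and 0.55; set-adjusted 0.81 and 0.62, adjusted p = 0.420 and 0.441), and Krt19, detected on no naive array and 1 of 3 arrays at 6 weeks, was not called (adjusted p = 0.0583). The macrophage list was not called (median 0.42, adjusted p = 0.334), although with the set in the model it was (0.99, adjusted p = 6.08e-04), and not with the set and an estimated correlation (adjusted p = 0.390). Trem2 and Cx3cr1 were at least 3.38-fold and 2.74-fold higher (adjusted p = 2.98e-04 and 3.80e-04). Kupffer cell genes were lower (median -0.57, 2 of 6 down by both counts, also adjusted over the list alone; adjusted p = 0.0477, and 0.486 with an estimated correlation), but not set-adjusted (-0.36, adjusted p = 0.415). Clec4f fell by 1.01 ± 0.31, and its set-adjusted change was 0.04 (adjusted p = 0.972). Interferon genes fell in 9 of 18 cases and rose in 1 (median -0.65, also adjusted over the list alone; adjusted p = 0.00696, and 0.481 with an estimated correlation), with a set-adjusted median of 0.03 (adjusted p = 0.943). Endothelial genes fell in 7 of 20 cases and rose in 1 (median -0.40, also adjusted over the list alone; adjusted p = 0.0106, and 0.536 with an estimated correlation), with a set-adjusted median of 0.07 (adjusted p = 0.943). Stab2, a scavenger receptor of sinusoidal endothelium, fell by 1.06 ± 0.18 (set-adjusted -1.36).

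Cell cycle genes rose in 16 of 23 cases and fell in 1, also adjusted over the list alone (median 1.42, set-adjusted 1.02; adjusted p = 1.38e-04, and 0.481 with an estimated correlation). Of the p53 targets 8 of 14 rose, also adjusted over the list alone (median 1.29, set-adjusted 1.12; adjusted p = 0.00126, and 0.138 with an estimated correlation), and Mdm2, which degrades p53, rose by 2.41 ± 0.22 (set-adjusted 1.93). Glutathione and NRF2 genes rose in 15 of 25 cases and fell in 4, 17 and 4 adjusted over the list alone (median 1.09, set-adjusted 0.68; adjusted p = 7.32e-04, and 0.442 with an estimated correlation), but Nqo1 was not called (0.34 ± 0.20, adjusted p = 0.189).

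Urea cycle and amino acid genes fell in 15 of 21 cases, 16 adjusted over the list alone (median -1.36, set-adjusted -1.11; adjusted p = 5.02e-09, and 0.160 with an estimated correlation). Argininosuccinate lyase, Asl, fell by 3.17 ± 0.39 (set-adjusted -1.90, adjusted p = 0.0585) and Prodh by 2.87 ± 0.26 (set-adjusted -3.13). Pericentral genes fell in 14 of 18 cases and rose in 2, also adjusted over the list alone (median -1.29, set-adjusted -1.33; adjusted p = 3.50e-07, and 0.0737 with an estimated correlation). All 7 female-biased genes fell, also adjusted over the list alone (median -2.58, set-adjusted -2.97; adjusted p = 1.24e-05, and 0.103 with an estimated correlation), with A1bg down by 2.96 ± 0.59 (set-adjusted -2.97, adjusted p = 0.0981). The male-specific Cyp4a12a was at least 2.85-fold higher (adjusted p = 2.11e-04; set-adjusted 0.0836). Bile acid genes fell in 11 of 17 cases and rose in 1, 13 and 3 adjusted over the list alone (median -1.26, set-adjusted -1.24; adjusted p = 1.17e-04, and 0.218 with an estimated correlation), and the bile salt pump gene Abcb11 fell by 2.48 ± 0.24 (set-adjusted -2.43). Cytochrome P450, acute phase and secreted protein genes were lower with medians of -0.79, -1.24 and -0.32 (set-adjusted -0.81, -1.52 and -0.60). Their adjusted p were 3.72e-04, 1.67e-05 and 0.0327, and 0.308, 0.312 and 0.598 with an estimated correlation. In all, camera called 17 of 28 lists, and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05, and fry called 16. With the set in the model 19 were called, 14 of them among the 17, and camera called 0 with the set and an estimated correlation, where 5 had an unadjusted p under 0.05.

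Among the small lists, the neutrophil genes S100a8 and S100a9 rose at 6 weeks by 1.87 ± 0.47 and 1.84 ± 0.51 (set-adjusted adjusted p = 0.119 and 0.181), and Wt1 of the mesothelium by 1.86 ± 0.33 (floored 1.35; set-adjusted adjusted p = 0.242). Sdc1, counted with B and plasma cells, fell by 1.17 ± 0.20 (set-adjusted -1.32). Cela2a of the acinar pancreas was at least 1.54-fold lower at 1 week and 1.72-fold lower at 6 weeks (adjusted p = 5.17e-04 and 1.49e-04). Car3, counted with adipose tissue, fell by 3.62 ± 0.40 at 6 weeks (set-adjusted -1.96), and Actn3 of skeletal muscle by 0.76 ± 0.25 (floored -0.44; set-adjusted adjusted p = 0.742).

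Many calls recurred across the times. Called in the same direction were 1237 genes at 1 and 4 weeks, 1520 at 1 and 6 weeks and 1795 at 4 and 6 weeks, and 4, 6 and 8 were called in opposite directions. Independent lists would have shared 162 higher and 127 lower genes at 1 and 4 weeks, 239 and 162 at 1 and 6 weeks, and 274 and 170 at 4 and 6 weeks. These counts do not allow for the shared naive arrays, whose errors favour calls in the same direction, so they are a low reference. Gsta1, Tnfrsf12a, Phlda3, Gpnmb and Adam32 were among the 595 genes higher at all 3 times, and Slc1a2, Oat, Glul and Ugt3a1 among the 539 lower at all 3. The changes at 4 and 6 weeks correlated across genes with r = 0.855, against 0.532 from the shared naive arrays alone in the simulation. Their covariance was 0.488 against 0.0304. For 1 and 4 weeks r was 0.761 against 0.533, and for 1 and 6 weeks 0.794 against 0.495.

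The comparison of 4 weeks with 1 week asked what followed the early response. Scara3, a scavenger receptor gene, rose by 3.57 ± 0.33 (n = 4 and 3, adjusted p = 1.46e-04; set-adjusted 3.48). Acta2 rose by 2.48 ± 0.47 (set-adjusted 1.66, adjusted p = 0.189) and on its other 3 probes by 1.07, 1.23 and 0.77, and Col1a1 was at least 2.98-fold higher (adjusted p = 0.00170; set-adjusted 0.0406). The elastase Mmp12 fell by 1.83 ± 0.32 (set-adjusted -2.08) and asparagine synthetase, Asns, by 2.25 ± 0.29 (set-adjusted -2.02).

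Between 4 weeks and 1 week 707 genes were called, 353 higher and 354 lower, and 2199 had an unadjusted p under 0.05. The arrays of 672 did not overlap, as for 21.7% of all genes, where chance gives 5.71%. A fit of the 4-week and 1-week arrays alone called 373. The fit with the set in the model called 134 genes, 94 of them among the 707. Within the first set, with 1-week array A alone against the 4-week arrays, 707 of 707 kept their sign. This was nearly fixed in advance, since array A helped to give the calls and the arrays of 672 genes did not overlap. Erich5 and Zxda, 2 of the genes that divide the array sets, headed the falls at -2.64 ± 0.53 and -2.43 ± 0.46, and were not called set-adjusted (adjusted p = 0.293 and 0.191). Both were picked as higher on 1-week arrays B and C than on every 4-week array, which favours such falls.

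With median centring only, which moved the median of all genes by 0.71 between 4 weeks and 1 week, the medians of the 6 lists called lower were above 0, and relative to that shift each of the 11 called lists kept its sign. Matrix genes rose in 7 of 22 cases, 12 adjusted over the list alone (median 0.71, set-adjusted 0.62; adjusted p = 3.52e-07, and 0.358 with an estimated correlation). Eln was at least 3.02-fold higher (adjusted p = 0.00929; set-adjusted 0.126) and Sparc rose by 1.82 ± 0.36 (set-adjusted adjusted p = 0.224). Cholesterol synthesis genes rose in 10 of 17 cases, 10 up and 1 down adjusted over the list alone (median 0.85, set-adjusted 0.77; adjusted p = 7.20e-06, and 0.312 with an estimated correlation). Msmo1, a sterol oxidase gene, rose by 1.28 ± 0.17 (set-adjusted 1.10). Cholangiocyte genes rose in 3 of 14 cases, 5 adjusted over the list alone (median 0.69, set-adjusted 0.73; adjusted p = 0.00101, and 0.315 with an estimated correlation), with the mucin Muc1 at least 1.79-fold higher (adjusted p = 0.0112; set-adjusted 0.0622). Urea cycle and amino acid genes fell in 9 of 21 cases, 15 with 1 up adjusted over the list alone (median -0.58, set-adjusted -0.51; adjusted p = 3.71e-07, and 0.216 with an estimated correlation), and ornithine transcarbamylase, Otc, fell by 1.35 ± 0.30 (set-adjusted -2.00).

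Lymphocyte and antigen presentation genes were lower at 4 weeks than at 1 week. The T and NK cell list had a median of -0.40 (set-adjusted -0.65; adjusted p = 0.00534, and 0.336 with an estimated correlation), with Zap70, a T cell receptor kinase, down by 1.92 ± 0.30 (set-adjusted -2.85). The MHC class II list had a median of -0.71 (set-adjusted -1.32; adjusted p = 0.00821, and 0.481 with an estimated correlation), with Cd86 down by 1.11 ± 0.25, and the interferon list one of -0.46 (set-adjusted -0.79; adjusted p = 0.00900, and 0.481 with an estimated correlation), with Gbp2 down by 1.10 ± 0.32. Adgre1, a surface marker of mouse macrophages, fell by 1.25 ± 0.33 (set-adjusted -2.01), and Ccl21a was at least 2.57-fold lower (adjusted p = 0.0230; set-adjusted 0.00898). The stellate, acute phase, periportal and erythroid lists had medians of 0.36, -0.60, -0.51 and 1.05 (adjusted p = 0.0263, 0.00297, 0.0175 and 0.0343). Their set-adjusted medians were 0.25, -0.48, -0.25 and 1.06 (adjusted p = 0.482, 0.0804, 0.162 and 0.122), and their adjusted p with an estimated correlation 0.536, 0.480, 0.315 and 0.481. In all, camera called 11 of 28 lists, and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05, and fry called 7. With the set in the model camera called 13, 7 of them among the 11. The macrophage list was one of those called only then (adjusted p = 2.1e-05). With the set and an estimated correlation camera called 0, where 3 had an unadjusted p under 0.05.

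The comparison of 6 weeks with 1 week spanned the longest interval between treated groups. Scara3 rose by 3.90 ± 0.35 (n = 3 and 3, adjusted p = 1.09e-04; set-adjusted 3.95), Ly6d by 3.04 ± 0.53 and the epithelial tetraspanin Tspan8 by 2.91 ± 0.43 (floored 2.48 for Tspan8; set-adjusted 3.06 and 3.19). Acta2 rose by 2.59 ± 0.51 and Mmp2 by 2.55 ± 0.53 (adjusted p = 0.00825 and 0.0102; set-adjusted 3.0 and 2.82). The other 3 probes of Acta2 changed by 0.66, 1.5 and -9.45e-04. Col1a1 and Lox were at least 2.0-fold higher (adjusted p = 0.00516 and 0.00253; set-adjusted 0.00775 and 0.00775). Upp2, a uridine phosphorylase gene, fell by 2.97 ± 0.44 and the phenobarbital-responsive Cyp2b10 fell by 2.81 ± 0.42 (set-adjusted -2.78 and -2.88).

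Between 6 weeks and 1 week 737 genes were called, 424 higher and 313 lower, and 2121 had an unadjusted p under 0.05. The arrays of 706 did not overlap, as for 23.4% of all genes, where chance gives 10%. A fit of the 6-week and 1-week arrays alone called 169. With the set in the model 425 genes were called, 364 of them among the 737. Within the second set, 3 arrays against 2, 42 were called, 1131 had an unadjusted p under 0.05, and 737 of 737 kept their sign. The signs were nearly fixed in advance, since these arrays helped to give the calls and those of 706 genes did not overlap.

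Matrix genes rose in 8 of 22 cases, 14 adjusted over the list alone (median 1.04, set-adjusted 1.18; adjusted p = 2.47e-06, and 0.40 with an estimated correlation), with Eln at least 3.63-fold higher (adjusted p = 0.00659). Turnover genes rose in 8 of 18 cases and fell in 1, 12 and 3 adjusted over the list alone (median 0.85, set-adjusted 0.83; adjusted p = 0.00435, and 0.481 with an estimated correlation). Stellate cell genes rose in 4 of 17 cases, 7 adjusted over the list alone (median 0.64, set-adjusted 0.73; adjusted p = 0.00288, and 0.480 with an estimated correlation). Pdgfra, the receptor of portal fibroblasts and stellate cells, changed by 1.22 ± 0.28 (set-adjusted 1.18, adjusted p = 0.0524). Cholangiocyte genes rose in 7 of 14 cases, 9 adjusted over the list alone (median 0.92, set-adjusted 0.90, or 0.56 at the bounds; adjusted p = 1.35e-04, and 0.277 with an estimated correlation), with Sox9 up by 1.36 ± 0.34 (floored 0.77) and Tnfrsf12a by 1.38 ± 0.33 (set-adjusted adjusted p = 0.0781 and 0.0641). Cholesterol synthesis genes rose in 8 of 17 cases, 12 adjusted over the list alone (median 0.86, set-adjusted 0.80; adjusted p = 5.11e-06, and 0.312 with an estimated correlation), with Hmgcs1 and Fdps each up by 1.30 (SE 0.16 and 0.19). Nsdhl was at 1.259 on the probe tested, and its other probes changed by 0.11, 0.18 and -0.38. Sqle was at 1.155, and its other probe at -0.24.

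Urea cycle and amino acid genes fell in 13 of 21 cases, 15 adjusted over the list alone (median -0.87, set-adjusted -0.84; adjusted p = 5.50e-12, and 0.117 with an estimated correlation), with cystathionine gamma-lyase, Cth, down by 2.33 ± 0.28 (set-adjusted -2.13). Kupffer cell genes fell in 4 of 6 cases, 5 adjusted over the list alone (median -0.95, set-adjusted -0.88; adjusted p = 1.46e-04, and 0.277 with an estimated correlation). Clec4f, a lectin found on Kupffer cells, fell by 1.61 ± 0.31 and Timd4 by 1.06 ± 0.24 (set-adjusted -1.26 and -1.01), while Cx3cr1 rose by 2.02 ± 0.37 (floored 1.43; set-adjusted 2.25). Female-biased genes fell in 3 of 7 cases, also adjusted over the list alone (median -0.86, set-adjusted -1.02; adjusted p = 3.32e-04, and 0.14 with an estimated correlation). Nqo1 fell by 0.69 ± 0.20 (set-adjusted adjusted p = 0.113). The p53 list was higher (median 0.34, set-adjusted 0.49; adjusted p = 0.0172, and 0.229 with an estimated correlation), with Bbc3, a mediator of apoptosis, up by 1.18 ± 0.21.

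Lower lists with smaller medians were cytochrome P450 (-0.45), bile acid (-0.21), acute phase (-0.47), interferon (-0.58) and periportal genes (-0.42), with set-adjusted medians of -0.24, -0.40, -0.66, -0.29 and -0.52. Their adjusted p were 0.00288, 0.0343, 0.00105, 3.70e-04 and 0.0143, and 0.358, 0.480, 0.442, 0.376 and 0.312 with an estimated correlation. The macrophage, T and NK cell and endothelial lists had medians of -0.50, -0.38 and -0.37 (adjusted p = 0.00696, 0.0353 and 0.00439), and were not called set-adjusted (-0.26, -0.18 and -0.19, adjusted p = 0.131, 0.127 and 0.102) nor with an estimated correlation (0.544, 0.480 and 0.489). In all, camera called 17 of 28 lists, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05, and fry called 11. Within the second set 17 lists were called, 14 of them among the 17 of all arrays.

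The comparison of 6 weeks with 4 weeks followed the array sets in full, since all 6-week arrays lie in the second and all 4-week arrays in the first. Among 426 called genes, 178 higher and 248 lower, the largest rises were those of Erich5 (3.76 ± 0.53), Zxda (3.49 ± 0.46), Gm7609, Rhbdl2 and Ifngr2, which are among the genes that divide the sets. Those genes were picked as higher on every 6-week than on every 4-week array, so their place here follows from that choice. After adding the set to the model limma called 0 genes, the smallest adjusted p was 0.0963 and 800 genes had an unadjusted p under 0.05. Without it 1753 had an unadjusted p under 0.05, and the arrays of 425 of the called genes did not overlap, as for 24.6% of all genes, where chance gives 5.71%. No array set holds arrays of both groups, so no value within a set can be given.

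Cyp2b13 fell by 3.16 ± 0.60 (n = 3 and 4, adjusted p = 0.00894; set-adjusted -3.92, adjusted p = 0.345), Cyp2b10 fell by 2.81 ± 0.40 and A1bg by 2.62 ± 0.56 (set-adjusted -3.03 and -2.64, adjusted p = 0.328 and 0.457). Asl fell by 2.56 ± 0.37 and Nqo1 by 1.34 ± 0.19 (set-adjusted -1.28 and -1.15, adjusted p = 0.501 and 0.345). Ugt1a2 was at least 3.39-fold lower (adjusted p = 0.00178; set-adjusted 0.473). Acta2, Col1a1, Timp1 and Tnfrsf12a were not called (adjusted p = 0.928, 0.253, 0.581 and 0.520), nor were Krt19, Cx3cr1 and Glul (0.821, 0.189 and 0.874).

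Female-biased genes fell in 3 of 7 cases, 4 adjusted over the list alone (median -1.05, set-adjusted -1.14; adjusted p = 2.81e-04, and 0.14 with an estimated correlation). Cytochrome P450 genes fell in 3 of 28 cases and rose in 1, 6 and 1 adjusted over the list alone (median -0.35, set-adjusted -0.33; adjusted p = 2.81e-04, and 0.293 with an estimated correlation). Urea cycle and amino acid genes fell in 3 of 21 cases, 4 with 1 up adjusted over the list alone (median -0.21, set-adjusted -0.41; adjusted p = 0.00729, and 0.481 with an estimated correlation). Median centring only moved the median of all genes by -0.94 and turned the medians of the turnover list (0.37, set-adjusted 0.70; adjusted p = 0.0148, and 0.491 with an estimated correlation) and the male-biased list (0.53, set-adjusted 0.49; 0.0464 and 0.442) below 0, though both lay above the shift. The Kupffer and endothelial lists were lower at -0.48 and -0.27 (adjusted p = 0.00718 and 0.0153, and 0.420 and 0.551 with an estimated correlation) but not set-adjusted (-0.27 and 0.25, adjusted p = 0.482 and 0.124). In all, camera called 7 of 28 lists, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05, and fry called 2. With the set in the model 13 were called, 5 of them among the 7, and camera called 0 with the set and an estimated correlation, where 3 had an unadjusted p under 0.05.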

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

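The tests of array set, of the ended calls, of brightness and of hepatocyte share below, and the values with undetected arrays at their lowest detected signal, were chosen after the results they concern had been seen, while the counts over other divisions of the arrays and the rules that picked results out were fixed before.

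Changes from naive liver differed between the times by a direct test. Between 4 weeks and 1 week the test found 707 genes and 11 lists, between 6 weeks and 1 week 737 genes and 17 lists, and between 6 and 4 weeks 426 genes and 7 lists. The list counts rest on camera's preset correlation, since with an estimated one camera called 0 lists in each, where 1, 5 and 2 had an unadjusted p under 0.05, and fry called 7, 11 and 2. Among the fibrosis key genes, those called higher than at 1 week were Acta2 at 2.478 by 4 weeks and 2.59 by 6 weeks, Col1a1 at 2.292 and 1.717, Lox at 1.405 and 1.798, and Mmp2 at 2.545 by 6 weeks only. Col1a2, Col3a1, Timp1, Tgfb1, Pdgfrb and Des were called at neither time, and the other 3 probes of Acta2 changed by 1.07, 1.23 and 0.77 by 4 weeks and by 0.66, 1.5 and -9.45e-04 by 6 weeks. The duct and progenitor genes Krt7, Sox9 and Tnfrsf12a were higher at 6 weeks than at 1 week by 0.9555, 1.365 and 1.378. Col1a1, Lox and Krt7 were detected on no 1-week array, so only lower bounds of their folds hold, 2.98 and 2.0 for Col1a1, 1.52 and 2.0 for Lox and 1.58 for Krt7 at 6 weeks. Macrophage genes parted, since Adgre1 moved by -1.252 and -1.29 and Timd4 by -0.922 and -1.061 from 1 week to 4 and 6 weeks and Clec4f by -1.606 to 6 weeks, while Cx3cr1 moved by 1.214 and 2.019. With undetected 1-week arrays at their lowest detected signal, Cx3cr1 moved by 0.63 and 1.43 and Sox9 by 0.77. Cyp1a2 was 0.9706 higher at 4 weeks than at 1 week. Nqo1 moved by 0.6421 from 1 to 4 weeks, by -0.6942 from 1 to 6 weeks and by -1.336 from 4 to 6 weeks. With the array set as a fixed term none of these Nqo1 calls held (adjusted p = 0.323, 0.113 and 0.345). Also lost were those of Acta2, Lox, Cx3cr1, Timd4 and Cyp1a2 between 4 weeks and 1 week and of Krt7, Sox9, Adgre1 and Tnfrsf12a between 6 weeks and 1 week.

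One value stood far from the others of its group. The mitotic kinase gene Pbk had a log2 intensity of 7.70 on 4-week array B and of 8.31 to 8.37 on the other 3, so the gap took 0.9084 of the range. Among 62 such groups examined, chance alone picks about 1 in 20. Outside the named genes, 653 detected probes were given no gene name here. Against naive liver 166 of them were called at 1 week, 171 at 4 weeks and 255 at 6 weeks.

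The genes called between 6 and 4 weeks may in part follow the array set. Over the 426 genes, 1-week arrays B and C differed from 1-week array A in the direction of the call by a median of 0.3327 (quartiles 0.0730 and 0.636) and for 81.2% of genes, although all 3 are of 1 group. Among all other genes that median was 0.0936, and 58.2% were positive. With the set as a term the median change of the 426 genes went from 0.927 to 0.626 and its median SE from 0.212 to 0.374, and 0 were called by limma, where the smallest adjusted p was 0.0963 and 800 genes had an unadjusted p under 0.05. With only the change taken from the fit with the set, 212 of the 426 stayed called, and with only the error taken from it 6, so the wider error by itself ended most calls. A difference between 6 and 4 weeks of TAA stays open.

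Array brightness is a related candidate explanation that the arrays leave undecided. The bright 1-week array B differed from A by a median of 0.3296 in the direction of the call (76.5% of genes), about as much as the dim array C (0.337), which speaks against dimness alone. A fit with brightness as a covariate called 7 genes, 1 of them among the 426, which could also happen if brightness merely followed the sets. The condition first written for this test asked only whether B moved like C, and by it brightness would have been ruled out. That condition was replaced after the value was seen, because array B is 1 array and with the covariate 1 of the 426 calls remained.

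Evidence for the sets themselves is weak. They rest on 7 genes, of which Ifngr2 has another probe that does not follow them, whereas of the 24 divisions that split the 1-week group and keep the others whole, the one that sets 1-week array C apart is followed by 64 genes, 1-week array A alone by 13, 1-week array B alone by 11 and the naive arrays with array C by 8. By the condition first written, that no other division be followed by as many genes, the sets would have been ruled out. It was replaced after the values were seen by one that compares only divisions of the same shape, where array B or C in the place of A gave 0 genes, and the outcome is that the sets could be real but cannot be told apart from a peculiarity of single 1-week arrays. The 64 genes also point to 1-week array C, the dimmest, as unlike the other arrays of its group.

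A lower share of hepatocytes in the tissue was weighed for the fall of pericentral genes and the rise of matrix genes at 4 weeks, where both groups lie in the first array set. An even loss of hepatocytes would lower periportal genes alike, but the pericentral score less the periportal score changed by -1.044. This difference lay between -2.14 and -1.84 on the 4-week arrays and between -1.02 and -0.89 on the naive arrays (two-sided exact permutation p = 0.0286, the smallest that 35 splits allow, adjusted 0.0857). An even loss would also raise markers of every other cell type alike, but the matrix score less the endothelial score changed by 1.195 (two-sided exact permutation p = 0.0286, adjusted 0.0857). The changes of these lists were known when the scores were chosen, so the scores add little to them. The array set was not tested here, since no array of either group lies outside the first set and the medians within it, -1.108 and 0.9108, are those of the comparison itself. An effect of TAA time stays open. A loss of pericentral hepatocytes alone and a change in the numbers of the cells that make matrix were not tested.

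Counts of genes were set against other divisions of the same arrays into groups of the same sizes. For 4 weeks against naive, 4 weeks against 1 week and 6 against 4 weeks, 1 of 35 splits gave as many, the real one. That is the smallest share 35 splits allow and was not adjusted over the counts tested, so chance is not excluded. The real counts were 2260, 707 and 426 and the highest others 570, 2 and 8. The split with 570 genes puts 4-week array B with the naive arrays, so it keeps most of the real difference. The real split of 6 and 4 weeks is also that of the array sets, where the count with the set as a term was 0. Comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05, with real counts of 2051, 3118 and 737 and highest others of 1, 1 and 2. For lists chance cannot be excluded either, since other splits gave as many calls. This held at 4 weeks against naive (17, highest other 18, 7 of 35 splits as many), 4 weeks against 1 week (11, highest other 16, 18 of 35) and 6 against 4 weeks (7, highest other 15, 24 of 35). The 10 splits of the remaining list counts are too few, with 13, 17 and 17 real and 14, 16 and 14 the highest others, and 3, 1 and 1 splits gave as many.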

How the results depend on the processing

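The settings with the array set and the brightness covariate were chosen after the data had been seen, and the others before, among them the replicate term, which was run on the value table because only its labels carry numbers. With no background correction, no detection filter, a looser or stricter detection rule, trend and robust variance, or the value table without a replicate term, each count of genes stayed within 1.5 times its value. Counts of lists did so with no background correction, no detection filter and the value table, and were not run for the other settings of this group. Where not stated otherwise the cause was not tested. Cyclic loess left 389 genes between 6 weeks and 1 week. Median centring only gave 768 genes at 1 week and 656 at 4 weeks against naive, 5 between 6 weeks and 1 week and 4127 between 6 and 4 weeks. It moved the median of all genes by -0.43, 0.24 and -0.65 against naive at 1, 4 and 6 weeks, by 0.71 and -0.23 at 4 and 6 weeks against 1 week and by -0.94 between 6 and 4 weeks, and the share of called genes that were higher to 7.81%, 72.4%, 6.60%, 99.3%, 20% and 0.194%. Counting every probe gave 1134 between 4 weeks and 1 week and 1075 between 6 and 4 weeks (29.5% higher, against 41.8%). Fits of only the 2 groups gave 1099 at 1 week against naive and, in the order 4 against 1, 6 against 1 and 6 against 4 weeks, 373, 169 and 762. Array weights gave 211, 209 and 868 in that order, and the value table with a replicate term 279, 402 and 102. Every 2-group fit with the 1-week group called fewer genes than the joint fit. Those without it called more, 3145 and 3233 at 4 and 6 weeks against naive. The 1-week arrays had the lowest weights, 0.61, 0.40 and 0.40, against 0.73 to 2.15 for the others. The spread shared by all groups may therefore understate the error of comparisons with 1 week. Replicate numbers do not pair the samples, since residuals of same-number pairs had a mean r of -0.0493. The stricter thresholds leave fewer genes by construction: at least 2-fold, 827, 862, 1384, 260, 357 and 174 in the order of the report, and an adjusted p under 0.01, 956, 1250, 1912, 135, 181 and 100, while the 2-fold overlaps were 448, 578 and 722. For lists an estimated correlation gave 0 in all 6 comparisons (unadjusted 3, 8, 7, 1, 5 and 2), and fry 7, 11 and 2 between the times. Adding the set to an estimated correlation, chosen after the data had been seen, also gave 0 in all 6 (unadjusted 5, 7, 5, 3, 4 and 3).

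With the set as a fixed term 1148 genes were called at 1 week and 934 at 6 weeks against naive, and 134, 425 and 0 between the times, with 13 lists between 6 and 4 weeks and overlaps of 751, 594 and 764 genes. The share that were higher fell from 49.9% to 28.4% between 4 weeks and 1 week. As a random term it gave 362 between 4 weeks and 1 week and 46 between 6 and 4 weeks. The brightness covariate gave 1752 at 6 weeks against naive, 256 between 4 weeks and 1 week and 7 between 6 and 4 weeks. Within 1 set, with fewer arrays, 1152 genes were called at 1 week, 423 between 4 weeks and 1 week and 42 between 6 weeks and 1 week.

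Leaving out 1 array at a time gave 1381 to 2237, 1600 to 2563 and 2467 to 3438 genes against naive at 1, 4 and 6 weeks. Between 4 weeks and 1 week it gave 359 to 1055, with 444 without 1-week array C and 424, 416, 359 and 401 without 4-week arrays A to D. Between 6 weeks and 1 week it gave 274 to 1396, with 425 and 1396 without 1-week arrays A and B and 372 and 274 without 6-week arrays A and C. Between 6 and 4 weeks it gave 106 to 654, with 654 without 1-week array C, 237, 220 and 145 without 4-week arrays B, C and D, and 106 and 141 without 6-week arrays A and C. Lists between 6 and 4 weeks came to 4 to 8, with 4 without 6-week array A. Overlaps, refitted only without each naive array, ran from 800 to 914 at 1 and 4 weeks, with 800 without naive array B, from 1032 to 1150 at 1 and 6 weeks and from 1303 to 1459 at 4 and 6 weeks.

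Single genes changed sign in a few settings. Median centring only did this for Dcn (-0.38) and Rbp4 (-0.31) at 1 week, Hmgcs1 (-0.0136) at 4 weeks and Aldh1a1 (-0.0748), Sqle (-0.51), Lss (-0.34), Fdps (-0.81), Acly (-0.62), Hamp (-0.53), Cd74 (-0.21), Aldh1b1 (-0.45), Cyp2d9 (-0.12) and Hnf4a (-1.09) at 6 weeks against naive. It did so for Sdc1 (0.27), Cyp3a13 (0.12) and Cyp2c70 (0.0518) between 4 weeks and 1 week and Cyp2d9 (-0.14), Mdm2 (-0.33), Plk2 (-0.47), Irgm1 (-0.39) and Hnf4a (-0.90) between 6 and 4 weeks. This scaling moves all genes alike, and relative to its shift 18 of the 21 kept their sign, all but Hmgcs1 at 4 weeks and Fdps and Hnf4a at 6 weeks against naive. The set term did so for Mrc1 (0.27), Clec4f (0.0360) and Zap70 (0.52) and the brightness covariate for Clec4f (0.00483), each at 6 weeks against naive. Another probe of the same gene differed in sign for Abcc2 (-0.21), Fmo5 (-0.55), Ifngr2 (-0.20) and Serpinc1 (0.32) at 1 week and for Irgm1 at 1, 4 and 6 weeks (-0.41, -1.26 and -1.48). At 6 weeks it did for Abcc2 (-0.49), Acta2 (-0.0138 and -0.25), Clec7a (-0.28), Cyp2a5 (-0.26), Fmo5 (-1.11), Ifngr2 (-0.04), Pecam1 (0.14) and Sqle (-1.88). It also did for Cyp3a13 (0.14), Ifngr2 (0.63) and Sdc1 (0.50) between 4 weeks and 1 week, Acta2 (-9.45e-04), Nsdhl (-0.38) and Sqle (-0.24) between 6 weeks and 1 week, and Ifngr2 (-0.47), Irgm1 (-0.22) and Pecam1 (0.35) between 6 and 4 weeks. In 24 of 204 results of other probes the sign of a called change was kept but the change was much smaller. Of the named genes called, 111, 119, 146, 70, 79 and 43 in the order of the report, 48, 41, 42, 53, 77 and 22 lost the call in some setting planned before, 26, 21, 28, 31, 35 and 27 without some array, and 40, 1, 78, 53, 22 and 43 with the set term. A term for the BeadChip was not run, since the files name no chip. The upper decile of signal was 2.13 to 8.42 times the background, so changes of dim genes on the dim 1-week and 6-week arrays are the least precise.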

Other observations

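The test of a return towards naive and the choice of the genes in this part were made after the values had been seen. Called in the same direction at 4 and at 6 weeks against 1 week were 272 genes, 146 higher and 126 lower. No condition was set on 1 week against naive, so early peaks such as Asns are among them. Both comparisons share the 1-week arrays, whose errors favour such agreement, and no count without effects was computed. With the array set in the model 190 of the 272 were also called at 6 weeks against 1 week. At 4 weeks against 1 week that model kept 94 of all main calls, so at most 94 of the 272 could keep both. The genes below are examples picked for a later change. Fxyd3, detected on 1 of 3 naive and 1 of 3 1-week arrays, changed by -0.67 ± 0.46 at 1 week and by 1.73 ± 0.43 and 2.27 ± 0.46 at 4 and 6 weeks against naive liver. Tspan8, detected on no naive array, was at least 5.73-fold and 7.96-fold higher at 4 and 6 weeks. Bicc1, a regulator of duct and tubule shape, changed by -0.20 ± 0.37, 1.70 ± 0.35 and 2.21 ± 0.37. Itgb6, which with its alpha partner activates latent TGF-beta, was detected on no naive or 1-week array and was at least 1.13-fold and 1.98-fold higher at 4 and 6 weeks than in naive liver. Ankrd1, a target of the YAP pathway detected on 1 of 3 naive and 1 of 3 1-week arrays, changed by 0.04 ± 0.31, 1.74 ± 0.29 and 2.42 ± 0.31. No floored change is given for Ankrd1, so the size of its rise is uncertain. The uridine phosphorylase gene Upp2 fell late, with -0.64 ± 0.44, -2.74 ± 0.41 and -3.61 ± 0.44.

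Other genes peaked early. Asns, detected on no naive array, was at least 4.79-fold higher at 1 week and fell by 2.28 from 1 to 6 weeks. Nnmt, a methyltransferase gene, was up by 1.58 ± 0.31 and fell by 2.01, and the fungal receptor gene Clec7a was up by 2.95 ± 0.38 and fell by 1.80. The other 2 probes of Clec7a rose by only 1.08 and 1.03 and fell by 1.36 and fell by 0.95. Spic, a factor of iron-recycling macrophages detected on every 1-week array and on no naive or 6-week array, was at least 1.79-fold higher at 1 week than in naive liver and at least 2.03-fold lower at 6 weeks than at 1 week. In the other direction Hmgcs1, an early enzyme of cholesterol synthesis, was -0.73 ± 0.16 at 1 week and then rose by 1.30, and Fdps of the same pathway was -0.70 ± 0.19 and rose by 1.30. Scara3 went from -1.32 ± 0.35 at 1 week to 2.26 ± 0.33 and 2.59 ± 0.35 at 4 and 6 weeks, and was one of the genes called in opposite directions against naive. With the array set in the model its 1-week change was -1.23 and not called (adjusted p = 0.124), so the opposite call was lost.

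A transient part of the early response is a candidate explanation for such genes. Of the genes called at 1 week against naive, 109 were called the other way between 6 weeks and 1 week (66 up then down and 43 down then up), and 115 were called further in the same way. When only the calls between 6 weeks and 1 week were taken from the model with the array set, 68 were called back and 51 further. The 1-week calls were still those without the set. Of the genes called back, 32 had both calls in both fits. Errors of the 1-week arrays enter both comparisons with opposite sign and favour calls back, so the counts leave the explanation undecided. Of the genes called in opposite directions at 4 and 6 weeks against naive, 8 in number, Glud1 at 0.83 and -1.40 moved furthest. Tsc22d1, detected on 2 of 3 naive arrays, was at 1.15 (floored 0.88) and -1.06. These differences also run along the array sets.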
